A study of Rattus norvegicus with 15 samples.

How the data were processed

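RNA from knee articular cartilage of male Sprague-Dawley rats was measured on 15 Affymetrix expression arrays. OA was induced in 5 rats by transection of the anterior cruciate ligament and partial removal of the medial meniscus, and 5 other rats had sham surgery. Each group of 5 arrays came from the operated knee of the OA rats (OA), their other knee (contralateral) or the operated knee of the sham rats (sham). All rats walked on a rotating cylinder for 30 minutes 3 times per week, and cartilage was taken 28 days after surgery. Per the labels, the tissue was dissected and homogenized at once, and the RNA went through 2 rounds of amplification. The labels do not name the software, the summary method or the scaling of the arrays.

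The deposited values are a ratio of each probe set to its own median over the 15 arrays, on a linear scale. The median of a probe set was 1 (to within 0.001) for 83.0% of probe sets, below 1 for 5288 and above 1 for 0, a pattern that division of dim probe sets by a fixed floor would leave, though no label states it. The lowest ratio was 0.01, which 95 values of the table held; none of them lay in a probe set that was tested. No intensity is left in the table, so expression levels cannot be compared between genes, and signal over background cannot be given. The number of arrays limits the precision.

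The ratios were log2 transformed with no constant added. Of 31099 probe sets, 57 control probe sets and the probe sets with a median below 1, taken as dim, were left out, which left 25760 for the tests. Array medians of the log2 ratio spanned 0.117 and 75th percentiles 0.169, below the limit of 0.2 set for adding a normalization, so none was added. The comparisons, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. Several steps had been planned for intensities and were replaced once the values proved to be ratios: a constant of 16 before the log, a filter at the 30th percentile of the mean, a prior variance that follows the mean, and the choice of the probe set with the highest mean for each gene.

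The platform table pairs 20826 of the probe sets with 1 gene symbol, 436 with several and 9780 with none. Of those with 1 symbol, 20758 carried a symbol of the rat gene table. For lists and named genes, each of 12743 genes was represented by 1 probe set, chosen by the suffix and then the lowest number of its identifier. Coordinates are not given, since the files name no genome build.

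The 3 groups were fitted together with limma 3.58.1 in R 4.3.3 (group means, 12 residual degrees of freedom, eBayes with a constant prior variance, two-sided), and p-values were adjusted by Benjamini-Hochberg over the 25760 probe sets of each comparison. The threshold was an adjusted p of 0.05. OA and contralateral knees belong to the same 5 rats, but no label says that a replicate number is an animal, so the fit took no account of pairs. Errors of fold changes are standard errors from limma, and group values are means with the SD over 5 arrays.

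A total of 28 gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 28 lists, and again with an estimated correlation and with fry. List means per array were also compared by exact permutation tests. They covered cartilage matrix, chondrocyte regulators, hypertrophy and mineralisation, matrix proteases, protease inhibitors, inflammatory mediators, EGF receptor signalling, TGF-beta and BMP signalling, contractile and cytoskeletal genes, Wnt signalling, fibroblastic matrix, cell cycle, glycolysis and hypoxia, oxidative phosphorylation, immediate early genes, unfolded protein response, antioxidant and metallothionein genes and interferon response. The others held markers of monocytes and macrophages, synovial fibroblasts, endothelial cells, bone-forming cells, osteoclasts, erythroid cells, neutrophils and marrow cells, skeletal muscle and adipocytes. Of 558 listed symbols 450 were tested, and 7 of these stood in more than 1 list. A further list and a gene are not reported here, though the list stayed in the adjustment and the counts. How many of the markers cartilage itself expresses cannot be read from ratios.

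The genes named were the 8 largest rises and the 8 largest falls among genes past the threshold whose 2 groups did not overlap, the 5 lowest p-values where fewer than 5 genes passed, and up to 4 members of each list past the threshold, or the 1 with the lowest p where none passed. Sox9, Acan, Col2a1, Col10a1, Mmp13, Adamts5, Tgfa, Ccl2, Cxcr4, Ednra and Ptgs2 were among those to be named in any case, but Sox9 and Ednra had no probe set with a single symbol. Lum and Eng were added after their values were seen.

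The pipeline was tested on simulated data with 200 of 25760 probe sets changed, over 20 draws per comparison. For OA versus sham it recovered 16.3% of the 1.5-fold, 58.7% of the 2-fold and 88.8% of the 4-fold changes, with 4.27% false calls. For OA versus contralateral the shares were 17.0%, 59.3% and 89.3%, with 5.62% false calls. Simulated contralateral and sham groups without changes gave a mean of 0.05 calls. All simulations drew each probe set independently of the others, whereas real probe sets can move together. RNA quality was measured as the log2 difference between 3′ and 5′ control probe sets of beta-actin, Gapdh and hexokinase and compared by exact permutation tests. The share of equal values between any 2 arrays was at most 0.232%, so no array was a copy of another. Other scalings, filters, variance models, array weights, covariates, blocks, set tests and leaving out each array were tried. Per comparison 100 splits of the arrays were drawn, the real one included. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.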

Results

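The data are log2 ratios of 15 arrays, 5 from the operated knee of rats with surgically induced OA, 5 from the contralateral knee of the same rats and 5 from the operated knee of sham rats. The series asks which genes of articular cartilage change in early experimental OA. Every log2 ratio below is relative to the probe set's median over all arrays, and every group value has n = 5 arrays. Array medians of the log2 ratio lay between -0.12 and 0.00.

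The comparison of OA with sham knees asks what the joint injury changed beyond surgery itself. Tnn, a tenascin of the extracellular matrix, was 25.1-fold higher in OA knees, with log2 ratios of 3.81 ± 0.95 (SD, n = 5) against -0.84 ± 0.55 in sham knees. The monocyte chemokines Ccl2 and Ccl7 rose by a log2 of 3.91 ± 0.54 and 3.02 ± 0.45 (SE). Crabp2, which carries retinoic acid, rose 8.51-fold, and the basement membrane chain Lamb1 rose 7.37-fold. Serpina1, an inhibitor of neutrophil elastase, rose 6.48-fold (log2 2.70 ± 0.22 SE, limma's adjusted p = 8.56e-05). Ptges, the synthase of prostaglandin E, rose 6.31-fold in the probe set that represents it, while its second probe set gave a log2 change of 0.23 and did not pass. C1qtnf3, a secreted protein of growing cartilage, rose 6.27-fold. The 5 OA values lay above the 5 sham values for each of these 8 genes, and their adjusted p ranged up to 0.0104 for Lamb1. Tnn, Crabp2 and C1qtnf3 were no longer past the threshold where the prior variance followed the mean log2 ratio, with adjusted p of 0.978, 0.839 and 0.514. Here and below, that mean is one of ratios and moves with a change in 1 group alone. This variance model therefore cannot decide how firm such calls are. With the mean of the macrophage markers as a covariate 4 of the 8 passed (Tnn, Crabp2, Serpina1 and C1qtnf3), and with that of the synovial fibroblast markers 1, Serpina1. With a robust prior variance that followed the mean Tnn and Crabp2 had adjusted p of 0.0506 and 0.0505.

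Single members of the fixed lists rose as well. Inhba, a chain of activin, rose 5.90-fold (log2 2.56 ± 0.23 SE) in OA against sham knees. The aggrecan-cleaving protease Adamts4 rose 4.12-fold (log2 2.04 ± 0.20 SE), and the elastase Mmp12 rose 3.68-fold (log2 1.88 ± 0.38 SE). Among genes of fibrous tissue Postn rose 4.75-fold, Col12a1 3.26-fold, the hyaluronan receptor Cd44 3.18-fold and Tnc 2.83-fold. The second probe set of Cd44 gave a log2 change of 0.82 and did not pass. The synovial fibroblast marker Cthrc1 rose 3.27-fold, the Wnt-linked Ccn5 3.15-fold and Panx3, a channel of maturing chondrocytes, 2.76-fold. Flna, which crosslinks actin, rose 2.18-fold, Klf4 1.94-fold, the EGF receptor ligand Hbegf 1.94-fold and the protease inhibitor Timp1 1.84-fold. Tgfa, another ligand of that receptor, rose 2.08-fold (log2 1.06 ± 0.24 SE, limma's adjusted p = 0.0209, n = 5), but without OA 1, OA 2 or sham 5 its adjusted p was 0.0508 to 0.0544. Other members of the lists of Timp1, Inhba and Klf4 fell, among them Timp4, Bmp4 and Nr4a1. These calls ended in 9, 7 and 8 of 10 fits without 1 array (adjusted p up to 0.107, 0.105 and 0.101).

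The strongest falls included 2 muscle genes, Mybpc1 and Tcap. Csap1, a salivary protein gene, fell 17.3-fold and Npw, which encodes neuropeptide W, 16.4-fold. The muscle filament gene Mybpc1 fell 11.8-fold (log2 -3.56 ± 0.38 SE), and Tcap, which anchors titin, fell 6.93-fold. Dbp, a transcription factor driven by the circadian clock, fell 8.61-fold (log2 -3.11 ± 0.44 SE, limma's adjusted p = 0.0016), and the transcription factor Helt fell 6.92-fold. Nrk and Ptgds fell 7.53-fold and 6.23-fold. Nrk was not past the threshold without OA 2, OA 3 or sham 4, with adjusted p of 0.0511 to 0.0663. The same held for Ptgds without OA 1, OA 2, OA 3, sham 1 or sham 3, at 0.056 to 0.0693. Mybpc1, Csap1 and Nrk were not past it where the prior variance followed the mean, with adjusted p of 0.254, 0.0826 and 0.185. With the mean of the muscle markers as a covariate Mybpc1 and Npw passed (adjusted p = 0.0119 and 0.0233) and Csap1 did not (0.101). Without the 3 arrays numbered 1, Lamb1, Tcap, Nrk and Ptgds had adjusted p of 0.0816, 0.0645, 0.0955 and 0.13, and Mmp12 and Hbegf of 0.0887 and 0.0864.

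In cartilage genes, Cnmd, which keeps vessels out of cartilage, fell 3.80-fold (log2 -1.92 ± 0.20 SE, limma's adjusted p = 0.000187) in OA against sham knees. The Wnt antagonist Frzb fell 1.56-fold (log2 -0.64 ± 0.13 SE), with an adjusted p of 0.0513 where the prior variance followed the mean and 0.0848 without the arrays numbered 1. Ramp2, a partner of the adrenomedullin receptor, fell 2.04-fold, the stress gene Herpud1 2.09-fold, the immediate early gene Egr1 2.04-fold and Dgat2, an enzyme of fat synthesis, 2.37-fold. Of the genes fixed for naming, Col2a1 (log2 -0.79 ± 0.36 SE, adjusted p = 0.241 from limma), Acan (-0.20 ± 0.15, 0.50) and Col10a1 (-0.23 ± 0.17, 0.51) did not pass. Neither did Mmp13 (log2 1.28 ± 0.40 SE, adjusted p = 0.0803), Adamts5 (0.36 ± 0.11, 0.0726), Cxcr4 (1.30 ± 0.41, 0.086) and Ptgs2 (0.57 ± 0.30, 0.309). Adamts5 had an adjusted p of 0.0382 without sham 2, and Cxcr4 of 0.0441 without OA 4.

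**Figure D1:**
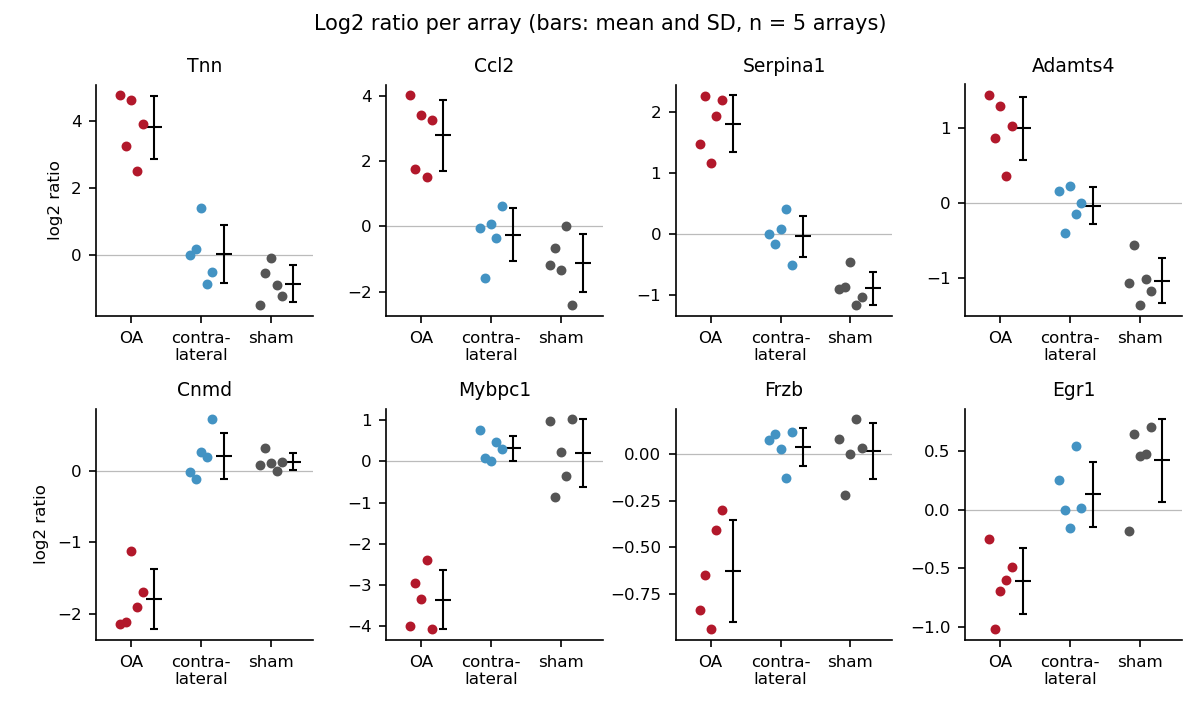
Log2 ratio of 8 genes on each of the 15 arrays (vertical axes) by group (horizontal axes), with bars for the mean and SD of 5 arrays. The 5 OA arrays lie apart from the 5 sham arrays in each panel, and the contralateral mean of Adamts4 (-0.03) lies between the OA (1.00) and sham (-1.04) means.

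Matrix proteases shifted up as a group in OA against sham knees (median log2 0.31, camera adjusted p = 3.8e-05, but 0.166 with an estimated correlation). Of 22 tested members 4 rose, Ctsc, Adamts4, Mmp12 and Ctsh, 0 fell and 18 did not pass, and 9 rose when adjusted over the list alone. Ctsc had adjusted p of 0.0626 to 0.0696 without OA 1, OA 3 or sham 1. Inflammatory mediators moved up (median 0.33, adjusted p = 0.00125, and 0.166 with an estimated correlation), with Ccl2, Ccl7 and Ptges the 3 members of 23 that rose and 4 adjusted over the list alone. In the fibroblastic matrix list (median 0.11, adjusted p = 0.003, and 0.383 with an estimated correlation) 5 of 26 rose, namely Postn, Col12a1, Cd44, Tnc and Lum, and 8 adjusted over the list alone. Contractile and cytoskeletal genes moved up (median 0.47, adjusted p = 2.96e-05, and 0.166 with an estimated correlation). Flna alone of 21 rose over all genes, and 8 rose adjusted over the list alone. The cell cycle list moved up (median 0.56, adjusted p = 1.09e-05, and 0.338 with an estimated correlation). Its 3 rises of 25 were Bub1b, Prc1 and Kif11, and 4 adjusted over the list alone. Bub1b had adjusted p of 0.0514 to 0.07 without OA 1, OA 3, OA 5, sham 1, sham 3 or sham 4. Cartilage matrix genes shifted down (median -0.42, adjusted p = 6.3e-05, and 0.338 with an estimated correlation), where Cnmd alone of 19 fell and 3 fell adjusted over the list alone. The call of the cartilage matrix list ended with the mean of the muscle markers (adjusted p = 0.0851) or of the synovial fibroblast markers (0.841) as a covariate. With the mean of the macrophage markers that of the cell cycle list ended (0.632), with the synovial markers that of the contractile genes (0.0551), and with muscle, macrophage or synovial markers that of inflammatory mediators (0.059, 0.22 and 0.342).

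Markers of other cell types shifted as well in OA against sham knees. Monocyte and macrophage markers moved up (median log2 0.77, adjusted p = 7.35e-08, and 0.166 with an estimated correlation), with 18 of 19 members higher. Of these Mrc1, Ctss and Cd14 rose, and 8 rose adjusted over the list alone. Mrc1 had adjusted p of 0.0507 to 0.103 without OA 1, OA 2, OA 3, OA 5, sham 1, sham 3, sham 4 or sham 5, and Ctss of 0.0521 to 0.0644 without OA 1, OA 3, sham 1 or sham 4. Synovial fibroblast markers moved up (median 0.56, adjusted p = 0.000132, and 0.166 with an estimated correlation). Of 12 members Cthrc1 and Col14a1 rose, and 4 adjusted over the list alone, while Col14a1 had adjusted p of 0.0571 to 0.118 without OA 1, OA 2, OA 3, OA 5, sham 1, sham 2 or sham 3. Endothelial markers moved up (median 0.53, adjusted p = 0.000242, and 0.166 with an estimated correlation). Of 14 members Emcn, Pecam1, Tek and Eng rose and Ramp2 fell, and 6 rose and 1 fell adjusted over the list alone. Eng, named after its values were seen, had an adjusted p of 0.0402. Tek had adjusted p of 0.0548 to 0.0656 without OA 1, OA 2, OA 3 or sham 1. Skeletal muscle markers moved down (median -2.21, adjusted p = 5.92e-05, and 0.338 with an estimated correlation), with all 14 tested members lower and 7 falls adjusted over the list alone. Acta1, skeletal actin, was the 1 member past the threshold over all genes (26.3-fold lower, log2 -4.72 ± 1.28 SE, adjusted p = 0.0496). Without OA 1, OA 2, OA 3, OA 5, sham 1, sham 3, sham 4 or sham 5 its adjusted p was 0.0623 to 0.114. Endothelial markers did not pass with the macrophage or synovial mean as a covariate (0.202 and 0.342), macrophage markers with the synovial mean (0.342) and muscle markers with the synovial mean (0.175).

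The remaining lists did not pass in OA against sham knees. Camera's adjusted p was 0.0612 for protease inhibitors and for Wnt signalling, 0.0686 for the unfolded protein response, 0.0787 for bone-forming cell markers, 0.0832 for EGF receptor signalling, 0.0888 for osteoclast markers and 0.099 for chondrocyte regulators. It was 0.155 for TGF-beta and BMP signalling, 0.159 for oxidative phosphorylation, 0.223 for erythroid markers, 0.227 for the interferon response and 0.316 for antioxidant and metallothionein genes. It was 0.365 for glycolysis and hypoxia, 0.578 for neutrophil and marrow markers, 0.911 for hypertrophy and mineralisation, and 0.958 for immediate early genes and for adipocyte markers. In the hypertrophy list the median was -0.19 while the mean was 0.10 and camera's direction was up. With an estimated correlation camera gave 0 lists past the threshold, and fry gave 11. By fry the cell cycle (adjusted p = 0.0625) and fibroblastic matrix (0.0685) lists did not pass, while protease inhibitors (0.00018, up), chondrocyte regulators (0.0193, down) and Wnt signalling (0.0387, up) did. In exact permutation tests of the list means per array, adjusted over the lists, cell cycle (exact adjusted p = 0.0606) and skeletal muscle (0.0635) did not pass and protease inhibitors (0.037, up) and chondrocyte regulators (0.0444, down) did.

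Over all probe sets, 1173 of 25760 passed in OA against sham knees, 567 higher and 606 lower, against 5118 at an unadjusted p under 0.05 (1288 expected by chance). Of the 1173, 1002 changed at least 1.5-fold. Without overlap between the groups were 1661 probe sets, where chance gives 204 (0.794%). The count was 769 without OA 1, 727 without OA 2, 559 without OA 3, 716 without sham 1 and 716 without sham 4. With the mean of the skeletal muscle markers as a covariate it was 106, with that of the macrophage markers 42 and with that of the synovial fibroblast markers 9. Of 64 named calls 48, 55 and 61 ended with these covariates, and Serpina1, Inhba and Cnmd passed with each of the 3. Without the 3 arrays numbered 1, 29 of the 64 ended (adjusted p 0.0506 to 0.192). That fit held fewer arrays per group, so lost power is part of this. With all arrays kept and a term for those numbered 1, 1169 of the 1173 calls were kept.

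The 2 knees of the OA rats were compared to ask which changes were confined to the injured joint. The contralateral knee was not operated on, so an effect of surgery itself is part of this comparison. Tnn was 13.6-fold higher in the OA knee (log2 3.77 ± 0.47 SE, limma's adjusted p = 0.00174, n = 5 per group). Crabp2 rose 7.24-fold, C1qtnf3 6.30-fold, Serpina1 3.60-fold and Col12a1 3.53-fold. F3, the tissue factor of coagulation, rose 5.39-fold (log2 2.43 ± 0.29 SE), Fndc1 5.07-fold and Inhba 3.19-fold. Ccl2 rose 8.27-fold, and its adjusted p was 0.0538 without OA 3. Mmp12 rose 4.27-fold, and its adjusted p was 0.0549 without OA 1 and 0.0583 without OA 3. P4ha3, an enzyme of collagen assembly, rose 3.91-fold, with adjusted p of 0.0563 to 0.0844 without OA 1, OA 3, OA 5, contralateral 1, contralateral 4 or contralateral 5. Adamts4 rose 2.05-fold (log2 1.03 ± 0.20 SE, adjusted p = 0.0279), and its adjusted p was 0.0526 to 0.0873 without OA 1, OA 2, OA 3, OA 5, contralateral 2, contralateral 4 or contralateral 5. Ptgs2, the inducible cyclooxygenase, rose 2.70-fold (adjusted p = 0.034). Without OA 1, OA 3, OA 5 or any 1 contralateral array its adjusted p was 0.0644 to 0.0996.

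Mybpc1 fell in the OA knee against the contralateral knee (12.8-fold, log2 -3.68 ± 0.38 SE, limma's adjusted p = 0.000509). Csap1 and Npw fell 13.4-fold and 6.84-fold. Without OA 3, contralateral 1, contralateral 2, contralateral 4 or contralateral 5 Csap1 had adjusted p of 0.0522 to 0.0909. Without OA 1, OA 2, OA 5, contralateral 1, contralateral 2 or contralateral 5 Npw had 0.0597 to 0.0826. Ska2l1 fell 6.47-fold with the lowest adjusted p of the comparison (0.00013), Styxl1 5.15-fold, and Myoc, which encodes myocilin, 4.29-fold. Sult2b1, a sulfotransferase, fell 4.34-fold in 1 of its 2 probe sets (log2 -0.68 in the other, not past), with adjusted p of 0.0649 to 0.0766 without OA 1, contralateral 1, contralateral 3, contralateral 4 or contralateral 5. Cnmd fell 4.01-fold (log2 -2.01 ± 0.20 SE) and Ramp2 2.22-fold (log2 -1.15 ± 0.14 SE). Frzb fell 1.58-fold (adjusted p = 0.0303; its second probe set, at log2 -0.47, did not pass), with 0.0609 to 0.0865 without OA 1, OA 2, OA 3, contralateral 1, contralateral 2, contralateral 3 or contralateral 5. Acan, Col2a1, Col10a1, Mmp13, Adamts5, Tgfa and Cxcr4 did not pass, with adjusted p of 0.363 for Adamts5 to 0.885 for Acan. Where the prior variance followed the mean, Tnn, Crabp2, C1qtnf3, F3 and Mybpc1 had adjusted p of 0.991, 0.918, 0.676, 0.668 and 0.403, Fndc1, Csap1 and Npw of 0.0632, 0.218 and 0.0841, and Frzb, Ska2l1 and Sult2b1 of 0.0939, 0.0686 and 0.0521.

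Of 28 lists 13 passed between the knees of the OA rats with the preset correlation, and camera with an estimated correlation gave 0, where the lowest adjusted p was 0.071, for adipocyte markers. The fibroblastic matrix list moved up (median log2 0.21, adjusted p = 1.05e-05, and 0.216 with an estimated correlation). Its rises were Col12a1 and Tnc, 2 of 26, with 8 adjusted over the list alone, and Tnc had adjusted p of 0.0536 to 0.0627 without OA 1, OA 3, contralateral 4 or contralateral 5. Synovial fibroblast markers moved up with 0 of 12 members past (median 0.64, adjusted p = 4.37e-05, and 0.0994 with an estimated correlation). Matrix proteases (median 0.19) and inflammatory mediators (0.17) both moved up with an adjusted p of 0.000229, and 0.123 and 0.0994 with an estimated correlation. Adamts4 and Mmp12 rose among the first (2 of 22, and 3 adjusted over the list alone), and Ccl2, Ptges (1 of its 2 probe sets, log2 0.49 in the other) and Ptgs2 among the second (3 of 23, and 7). Upward shifts were also called for Wnt signalling (median 0.23, adjusted p = 0.00151), protease inhibitors (0.33, 0.0118), contractile and cytoskeletal genes (0.26, 0.00151), endothelial markers (0.52, 0.00249) and macrophage markers (0.21, 0.00309). With an estimated correlation these had 0.101, 0.0994, 0.216, 0.249 and 0.441, and macrophage markers did not pass at the preset correlation either without contralateral 1. The members that rose in these lists were Sfrp4 (1 of its 2 probe sets, log2 -0.04 in the other) and Ccn5, Serpina1 and Timp1, Flna, and Pecam1, while Ramp2 fell and 0 macrophage markers passed. Without any 1 array but OA 4, Ptges and Flna had adjusted p of 0.0563 to 0.0964 and 0.058 to 0.105. Timp1 had 0.0718 to 0.11 without any 1 array but OA 2 or OA 4. Ccn5 had 0.0504 to 0.0706 without OA 1, OA 3, contralateral 1, contralateral 2, contralateral 4 or contralateral 5. Pecam1 had 0.0662 to 0.094 without OA 1, OA 2, OA 3, contralateral 2, contralateral 3 or contralateral 5.

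Skeletal muscle markers moved down most in this comparison (median -2.17, adjusted p = 4.79e-06, and 0.249 with an estimated correlation). All 14 members were lower in the OA knee, 0 passed over all genes and 8 fell adjusted over the list alone. Adipocyte markers moved down (median -0.61, adjusted p = 0.000646, and 0.071 with an estimated correlation) with all 9 members lower, 4 of them falls adjusted over the list alone. Their mean log2 ratio was -0.35 in OA, -0.30 in sham and 0.47 in contralateral knees, so both operated groups lay below the unoperated one. Fabp4, a fatty acid carrier with the lowest p among them, was 7.95-fold lower without passing (adjusted p = 0.0561). Cartilage matrix genes (median -0.22, adjusted p = 0.00203) and oxidative phosphorylation (-0.17, 0.0174) moved down, and with an estimated correlation had 0.452 and 0.61. The first of these did not pass without contralateral 1, and the second without OA 2 or OA 4. With the muscle or synovial mean as a covariate the calls of cartilage matrix (adjusted p = 0.87 and 0.662), oxidative phosphorylation (0.79 and 0.791), inflammatory mediators (0.0539 and 0.215), macrophage markers (0.334 and 0.167) and endothelial markers (0.0539 and 0.807) ended. With the synovial mean those of contractile genes (0.521) and Wnt signalling (0.0753) ended too. The remaining lists had adjusted p of 0.0617, for TGF-beta and BMP signalling, to 0.834. By fry 5 lists passed between the knees, protease inhibitors, inflammatory mediators, Wnt signalling, synovial fibroblast markers and adipocyte markers. In the exact permutation tests of the means per array 0 did (lowest exact adjusted p = 0.0556). Protease inhibitors, inflammatory mediators, skeletal muscle and adipocyte markers shared that value. Their exact p was 0.00794, the smallest 5 against 5 can give, so with no more lists at it none could pass. In the hypertrophy list median (-0.19) and test pointed down and the mean (0.01) up. For glycolysis and hypoxia the median (-0.02) was negative while mean and test were positive, and for immediate early, antioxidant and interferon genes medians and means were negative while camera's direction was up.

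Over all probe sets, 256 of 25760 passed between the OA and contralateral knees, 155 higher and 101 lower, against 3047 at an unadjusted p under 0.05. Of the 256, 244 changed at least 1.5-fold, and 939 of all probe sets had groups without overlap, where chance gives 204 (0.794%). The count was 100 without OA 1, 145 without OA 2, 92 without OA 3, 429 without OA 4, 155 without contralateral 2, 149 without contralateral 3, 115 without contralateral 4 and 91 without contralateral 5. Of 32 named calls, 29 ended with a robust prior variance that followed the mean (adjusted p 0.0516 to 0.223), Cnmd (0.0639), Ramp2 (0.065), Col12a1 (0.0594), Myoc (0.065) and Styxl1 (0.0607) among them, and Mmp12, Serpina1 and Inhba passed. Without the 3 arrays numbered 1, 16 of the 32 ended (0.0698 to 0.166), where lost power is again a part. With all arrays kept and a term for those numbered 1, 251 of the 256 calls were kept. The count over all probe sets was 21 with the robust prior variance and 138 with only these 2 groups fitted. It was 6, 153 and 2 with the mean of muscle, macrophage or synovial fibroblast markers as a covariate. With the replicate number as a fixed block, though no label says that a number is a rat, it was 38. That fit held only the OA and contralateral arrays and had fewer residual degrees of freedom, so lost power is part of this fall. With the number as a random block over all arrays, each of the 256 calls was kept. Of the 32 named calls 21 ended with the fixed block. Among them were Mmp12 (adjusted p = 0.0879), Serpina1 (0.0582), Crabp2, F3, Ramp2 and Styxl1 (0.0559 each) and Adamts4 (0.0643), while Inhba passed.

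**Figure D2:**
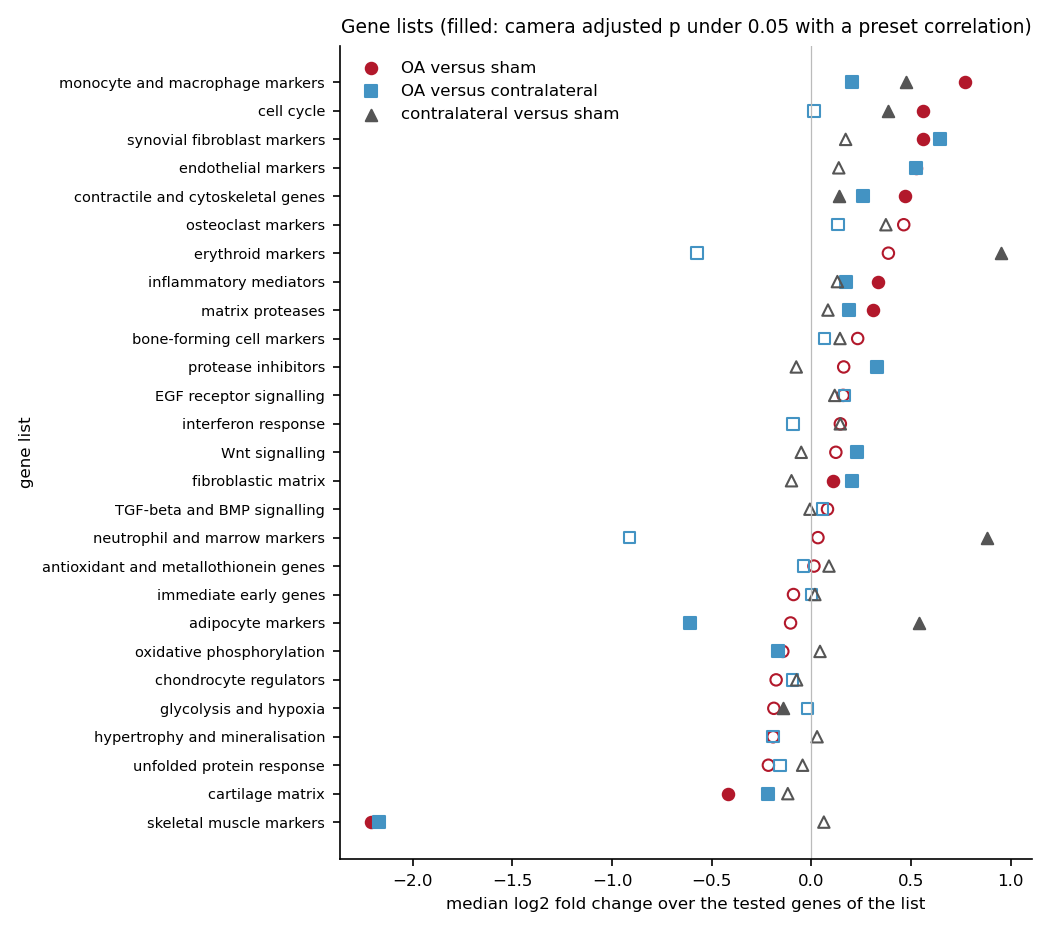
Median log2 fold change of the tested genes of each gene list (vertical axis), in log2 units (horizontal axis), for the 3 comparisons; filled symbols passed camera with the preset correlation. Skeletal muscle markers lie at -2.21 and -2.17 in the comparisons of OA knees and at 0.06 between contralateral and sham knees.

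Contralateral and sham knees were compared to ask whether the unoperated knee of the OA rats differed from a knee without induced OA. The sham knees had surgery and the contralateral knees had none, which this comparison cannot set apart from OA in the other knee. No probe set passed with limma adjusted over all 25760, and 1 gene, Medag, passed when each of 12743 genes was counted once. The gene with the lowest p was Medag, a gene of fat cell formation, with a value 3.17-fold higher in contralateral knees (log2 1.66 ± 0.23 SE, adjusted p = 0.10, n = 5), and its 4 probe sets ranged from 0.19 to 1.69. Ahsg, which encodes the serum protein fetuin, was 1.89-fold lower and Dbp 6.15-fold lower (log2 -2.62 ± 0.44 SE). The mitotic kinesin Kif2c was 5.15-fold higher, and Cfd, an adipocyte protease, 3.22-fold higher (log2 1.69 ± 0.31 SE). Their adjusted p was 0.179 for Ahsg, Dbp and Kif2c and 0.209 for Cfd. In each of these 5 genes the 5 values of 1 group lay apart from the 5 of the other. Adamts4 was 2.01-fold higher and Inhba 1.85-fold higher in contralateral knees, with adjusted p of 0.296 and 0.387, and Herpud1 was 1.74-fold lower (0.296). Acan, Col2a1, Col10a1, Mmp13, Adamts5, Tgfa, Ccl2, Cxcr4 and Ptgs2 had adjusted p of 0.505 for Tgfa to 0.962 for Col10a1.

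Of the lists, 7 passed between contralateral and sham knees with the preset correlation. Adipocyte markers moved up (median log2 0.54, adjusted p = 0.000526) and passed with an estimated correlation (0.048) and with fry (0.00787). They did not pass in the exact permutation test of the means per array (exact adjusted p = 0.111, the lowest of the 28 lists here). Their exact p before adjustment was 0.00794, the smallest 5 against 5 can give. With so few lists at that value none could pass. Of 9 members 5 rose and 1 fell adjusted over the list alone, and 0 passed over all genes. Cell cycle genes moved up, 23 of 25 being higher (median 0.38, adjusted p = 1.25e-08, and 0.598 with an estimated correlation). Macrophage markers moved up with 18 of 19 higher (median 0.48, adjusted p = 4.69e-06, and 0.598 with an estimated correlation). Erythroid markers (median 0.95, adjusted p = 0.0061), neutrophil and marrow markers (0.88, 0.0109) and contractile genes (0.14, 0.0201) moved up, and glycolysis and hypoxia genes moved down (-0.14, 0.0061), each with 0.638 with an estimated correlation. Erythroid markers did not pass without contralateral 2, neutrophil and marrow markers without contralateral 2 or contralateral 3, contractile genes without contralateral 3 or sham 1, and glycolysis genes without sham 1. Without contralateral 4, 12 lists passed. With the mean of the macrophage markers as a covariate only adipocyte markers passed, and cell cycle genes had an adjusted p of 0.456. The remaining lists had adjusted p of 0.0703, for endothelial markers, to 0.984, for skeletal muscle markers. Median and mean differed in sign for protease inhibitors (-0.08 and 0.07, test up), TGF-beta and BMP signalling (-0.01 and 0.05, up), Wnt signalling (-0.05 and 0.01, down) and immediate early genes (0.02 and -0.07, down).

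Over all probe sets, 0 of 25760 passed between contralateral and sham knees in limma, with 1902 at an unadjusted p under 0.05 against 1288 expected by chance. The count was 2 without contralateral 3, 1 without sham 2 and 1 without sham 5, where Medag passed without contralateral 3 (adjusted p = 0.046) and without sham 2 (0.018), and Kif2c without sham 5 (0.0165). Without overlap were 310 probe sets, where chance gives 204 (0.794%).

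**Figure D3:**
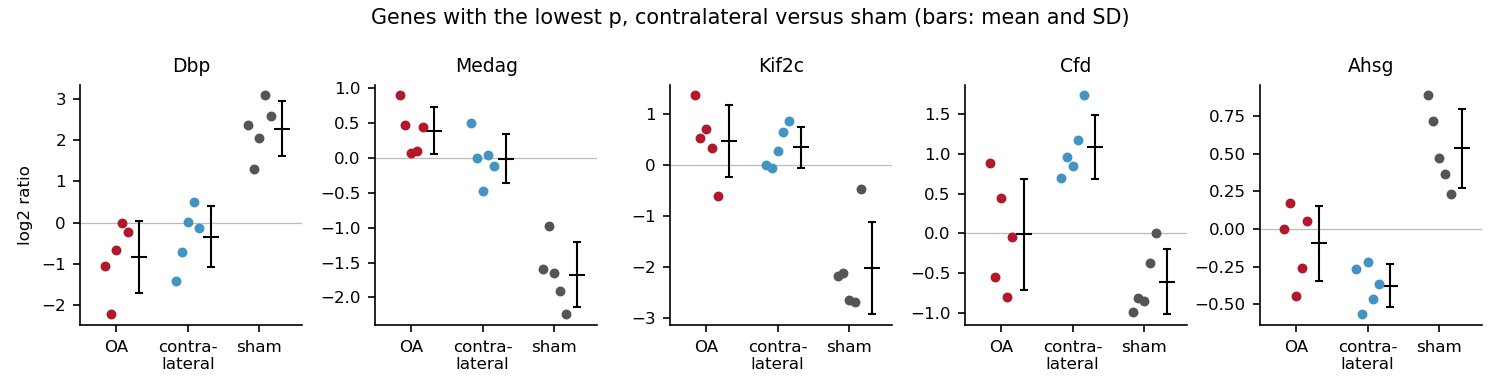
Log2 ratio per array (vertical axes) by group (horizontal axes) for the 5 genes with the lowest p between contralateral and sham knees, with bars for the mean and SD of 5 arrays. Dbp has means of -0.83 in OA, -0.35 in contralateral and 2.27 in sham knees.

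**Figure D4:**
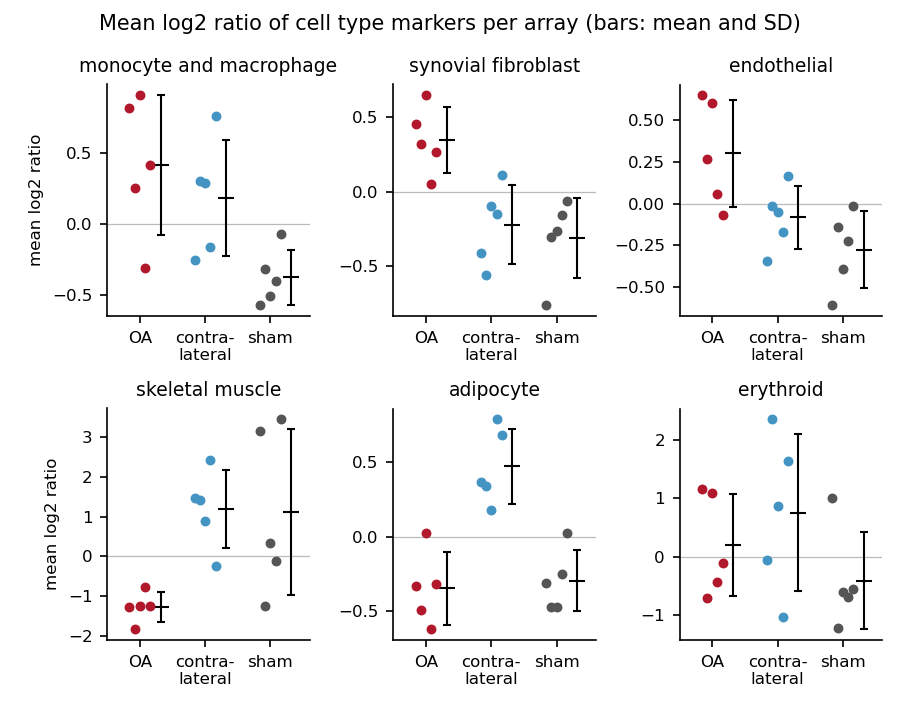
Mean log2 ratio of the tested markers of 6 cell types on each array (vertical axes) by group (horizontal axes), with bars for the mean and SD of 5 arrays. The skeletal muscle mean is -1.28 in OA, 1.19 in contralateral and 1.11 in sham knees.

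Genes such as Tnn, Serpina1, Inhba, Cnmd and Mybpc1 passed in both comparisons of OA knees. In all, 226 probe sets passed in both with the same direction, 134 higher and 92 lower, and 0 with opposite directions. Independent lists would share 3.41 higher and 2.38 lower, and simulated unchanged groups with the same 5 OA arrays in both comparisons shared a mean of 0. In another simulation, of contralateral against sham groups without change, a mean of 0.05 probe sets passed. If the simulated OA comparisons gave as few, they had little to share. With the OA arrays divided between the comparisons the overlap was a mean of 4.75 over 20 divisions (0 to 24). Each of those fits held fewer arrays, so lost power is part of this fall. The fold changes of both comparisons had a correlation of 0.693, against 0.501 in the simulated unchanged groups. Those groups had independent probe sets, so 0.501 does not show how far chance can move this correlation. With divided OA arrays it was a mean of 0.370. Of the 256 calls between knees 88.3% also passed against sham knees, and 30 did not. Without contralateral 5 the overlap was 84, and without OA 4 it was 377.

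Across probe sets, the fold changes of OA against sham and of contralateral against sham knees had a Pearson correlation of 0.592 and a covariance of 0.0893. Probe sets are not independent replicates, and both comparisons share the 5 sham arrays. Simulated unchanged groups with shared sham arrays gave 0.499 and a covariance of 0.0421. Their probe sets were drawn independently, so these values do not show how far chance can move the correlation of real arrays. Of 100 splits of the real arrays 18 gave a correlation at least as high as 0.592. With the sham arrays divided between the comparisons the correlation was a mean of 0.236 over 20 divisions (0.0773 to 0.336).

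The mean measure of RNA quality did not differ detectably between groups, while the difference for Gapdh, 1 of its 3 transcripts, was lower in OA than in sham knees. The 3′ minus 5′ log2 difference of the control transcripts was 0.54 ± 0.45 in OA, 0.42 ± 0.52 in contralateral and 0.78 ± 0.34 (SD, n = 5) in sham knees. Differences were -0.24 for OA minus sham, 0.12 for OA minus contralateral and -0.37 for contralateral minus sham (two-sided exact permutation p = 0.381, 0.675 and 0.214). For Gapdh alone OA minus sham was -0.20 and OA minus contralateral -0.23 (exact p = 0.0397 and 0.0556, not adjusted). For beta-actin these were -0.02 and 0.01 (exact p = 0.889 and 0.944). Hexokinase carried most of the spread of the mean, with group SDs of 0.95 to 1.54 against 0.10 to 0.21 for beta-actin and Gapdh. The mean could thus miss a shift in the less variable transcripts.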

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

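The tests of the muscle genes and of the strongest rises, with their covariates and the leaving out of the arrays numbered 1, were chosen after the data were seen.

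In 12 of 360 groups of 5 values, 1 array lay farther from the other 4 than 95% of such groups of a normal sample would allow, and chance alone gives about 1 in 20 groups, or 18. The gap to the nearest other array, as a share of the group's range, is given for each. Sham 1 lay low for C1qtnf3 (0.788, a log2 ratio of -1.06 against -0.11 or more), Mrc1 (0.855, -1.16 against -0.17 or more) and Egr1 (0.719, -0.18 against 0.46 or more). Sham 5 lay high for the mitotic genes Bub1b (0.753, -1.28 against -1.96 or less) and Kif2c (0.743, -0.47 against -2.11 or less). Sham 4 lay high for Chrd (0.884, 0.76 against 0.00 or less) and for the mean of the Wnt signalling list (0.728, 0.11 against -0.11 or less). OA 1 lay high for Klf4 (0.741, 1.02 against 0.50 or less) and low for Dgat2 (0.737, -1.41 against -0.63 or more). OA 3 lay low for Sult2b1 (0.795, -3.81 against -1.49 or more) and for the mean of the EGF receptor list (0.777, -0.20 against 0.10 or more). Contralateral 1 lay low for P4ha3 (0.768, -1.47 against -0.26 or more).

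Muscle transcripts were lower in OA knees, at a mean log2 ratio of -1.28 ± 0.38 (SD, n = 5) against 1.19 ± 0.98 in contralateral and 1.11 ± 2.08 in sham knees. Muscle carried into the dissected cartilage in varying amounts may be a source, since the 14 markers rose and fell together between arrays of 1 group (mean pairwise correlation 0.618). Ratios hold no level that would give the share of muscle, the labels name no sort of cells, and a lower muscle share after OA surgery and less carry-over in dissection were not set apart by a test. With the muscle score as a covariate Mybpc1 (log2 -3.56 to -2.76) and Npw (-4.03 to -4.31) stayed below -2 and past the threshold, so the score did not remove their falls. They were set apart from Csap1 by this same result, so it is not separate evidence against muscle as a cause. For Csap1 a muscle effect cannot be told apart from another cause: its fold moved from -4.11 ± 0.74 to -4.06 ± 0.99 (SE), and its call ended (adjusted p = 0.101) as the standard error grew.

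The 8 strongest rises were those of Tnn, Ccl2, Crabp2, Ccl7, Lamb1, Serpina1, Ptges and C1qtnf3. They might come from more macrophages or synovial fibroblasts in the OA samples or from the cartilage of injured joints, which stays open for all 8. A shift of the 3 arrays numbered 1 was considered too. Those arrays did differ from the others: a term for them in the fit had 413 probe sets past the threshold, 204 higher and 209 lower. Each group held an array numbered 1, so a shift shared by those arrays cancels between groups. With that term in the fit, 1169 of the 1173 calls in OA against sham knees were kept. Without the arrays numbered 1, 7 of 8 passed (median log2 2.95 to 2.69), which argues against those arrays as the cause, and Lamb1 did not (adjusted p = 0.0816). With the macrophage score as a covariate 4 of 8 passed, Tnn, Crabp2, Serpina1 and C1qtnf3 (median log2 2.84), and with the synovial fibroblast score 1 of 8, Serpina1 (2.70 to 3.07). These genes were set apart by that same result, so their passing is not separate evidence against such cells as a cause. Over all 8, 4 passing decides nothing about macrophages. That only 1 passed is what more synovial fibroblasts would give, but the median log2 of the 8 stayed at 2.68, so this stays open too. The calls of Ccl2, Ccl7, Lamb1 and Ptges with the macrophage score (median 2.52) and of the 7 other than Serpina1 with the synovial score (median 2.56) ended as standard errors grew (median of the 8 0.42 to 0.56 and 0.62) and most folds shrank. For these genes more such cells and a change within the cartilage cannot be told apart, since group takes 58.4% and 69.0% of the variance of the scores.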

How the results depend on the processing

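Covariates, the batch term and leaving out of the arrays numbered 1, the raised floor and the mean over probe sets were chosen after the data were seen; the rest was planned. The 50th-percentile filter and constants of 1 and 64 were not run, since ratios hold no level, nor were a random block and a robust trend for lists, which camera does not take. Causes were not tested unless stated.

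In OA against sham, scaling, filter, variance models, weights, the fit of 2 groups, the raised floor, the batch term and the hybridisation covariate gave 795 to 1482 probe sets and 10 or 11 lists, against 1173 and 10; genes counted once gave 784, and means over probe sets 13 lists. Probe sets fell to 106, 42 and 9 with muscle, macrophage and synovial scores as covariates and to 451 without the arrays numbered 1; lists fell to 5 with the synovial score and to 0 with an estimated correlation. Leaving out 1 array gave 559 (OA 3) to 1458 probe sets and 10 to 14 lists; the others that moved the count over 1.5 times were OA 1 (769), OA 2 (727), sham 1 (716) and sham 4 (716).

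In OA against contralateral, 256 became 21 with trend and robust, 138 with only the 2 groups, 6, 153 and 2 with muscle, macrophage and synovial scores, and 92 without the arrays numbered 1. Leaving out 1 array gave 91 (contralateral 5) to 429 (OA 4), with 100 for OA 1, 145 for OA 2, 92 for OA 3, 155 for contralateral 2, 149 for contralateral 3 and 115 for contralateral 4. The 13 lists became 8 with the muscle score, 8 with the synovial score, 5 with fry and 0 with an estimated correlation, and 11 to 17 without 1 array. Fewer arrays and degrees of freedom are part of the change where arrays are left out.

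No label says that replicate numbers are animals. Arrays of equal number correlated over 0.1 for 4 of 5 numbers (-0.08 to 0.21; mean 0.119 against -0.03 for unequal numbers, consensus 0.189), and 7 of 10 arrays matched best with their own number. As a fixed block they gave 38 probe sets between the knees (24 higher, 14 lower, 30 of them called without the block). As a random block over all arrays they gave 608, with each of the 256 calls kept. The fixed block left fewer residual degrees of freedom, so lost power is part of that difference. Of 32 named calls, 21 were not past the threshold with the fixed block (adjusted p 0.0546 to 0.183).

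In contralateral against sham, 0 became 2 with the batch term and 1 counted over genes, and 0 to 2 without 1 array (2 without contralateral 3, 1 without sham 2 or sham 5). The 7 lists became 1 with the macrophage score, 1 with an estimated correlation, 1 with fry, and 5 to 12 (contralateral 4) without 1 array.

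The overlap of 226 was 69 without the arrays numbered 1, 4.75 with divided OA arrays and 84 (contralateral 5) to 377 (OA 4) without 1 array. The correlation of 0.592 was 0.236 with divided sham arrays and 0.545 to 0.645 without 1 array. RNA quality in OA minus sham passed for Gapdh alone (-0.20) and was -0.35 to -0.06 without 1 array; OA minus contralateral was 0.01 to 0.31 and contralateral minus sham -0.55 to -0.26. The log2 change of Mrc1 in OA against sham was -0.0105 with the synovial score (limma's adjusted p = 0.998), so its rise vanished and no fall was detected. Of 64 named calls in OA against sham 44 kept theirs without each array and 55 under both scalings and no filter; of 32 in OA against contralateral, 15 and 27. With no intensity, what signal over background limits cannot be given.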

Other observations

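The tests of the clock genes were chosen after their values were seen, and the counts of other splits were set before.

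Dbp, the clock gene that fell 8.61-fold in OA against sham knees, was 1 of 14 clock genes looked at together. In OA against sham knees, 5 of 9 genes of the evening phase fell (Dbp, Hlf, Nr1d1, Per3 and Bhlhe41) and 3 of 5 of the opposite phase rose (Bmal1, Npas2 and Nfil3). The difference of the means of both phases was -0.92 ± 0.46 in OA, -0.43 ± 0.68 in contralateral and 1.33 ± 0.82 (SD, n = 5) in sham knees. OA minus sham was -2.25 and contralateral minus sham -1.76, each with an exact two-sided permutation p of 0.00794, the smallest 5 against 5 can give (0.0179 adjusted over 9 tests). OA minus contralateral was -0.49 (exact p = 0.198, adjusted 0.223).

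The contralateral shift was 0.782 of the OA shift, which argues against a process of the operated OA knee alone. In OA minus sham the evening genes shifted by -1.43 and the others by 0.82 (exact p = 0.00794 and 0.0238, adjusted 0.0179 and 0.0429). In contralateral minus sham they shifted by -1.17 and 0.60 (exact p = 0.00794 and 0.0635, adjusted 0.0179 and 0.0816), so only the evening genes passed there, and 0 of the 14 genes passed on their own in limma. The mean shifts were thus opposite in sign in 2 of 2 comparisons with sham knees. Both comparisons, and the share of 0.782, use the same sham arrays and so are not separate evidence, and Dbp, which prompted the look, is among the evening genes. Opposite shifts would follow if sham and OA rats were sampled at different times of day, but also if the clock of OA rats ran differently. These cannot be told apart, since the labels give no time of collection. Such a difference may enter any comparison with sham knees.

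Whether any split of the arrays would do as well was tested with 100 splits of the same arrays per result, the real one included. For OA against sham 1 of 100 splits gave as many probe sets as the real 1173 (highest other 5), so chance is an unlikely source of that count. The splits do not tell OA apart from another difference between OA and sham rats. For OA against contralateral 1 of 100 splits gave as many as the real one (real 256, highest other 94). These splits took no account of both knees coming from the same 5 rats, so chance cannot be excluded there. For the 226 probe sets shared by both, 1 of 100 splits gave as many (highest other 2), which adds nothing to these counts, since splits with almost no calls have almost none to share. It cannot be excluded for the counts of gene lists: 18 of 100 splits gave at least the real 10 lists in OA against sham (highest other 16), 8 gave at least 13 in OA against contralateral (17), and 22 gave at least 7 in contralateral against sham (14). It cannot be excluded for the 1902 probe sets at an unadjusted p under 0.05 in contralateral against sham, where 12 of 100 gave as many. The highest other there, 4087, put contralateral 1 and 4 with sham 1, 4 and 5. The correlation of 0.592 between the fold changes against sham was reached by 18 of 100 splits (highest other 0.727).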
